A study of Mus musculus with 5 samples.

How the data were processed

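RNA from whole kidneys of mouse embryos at embryonic day 15.5 was sequenced in bulk, with 2 libraries labelled NICD_mut and 3 labelled NICD_wt. NICD_mut kidneys carried the Six2TGC driver, a transgene from the Six2 locus that makes Cre recombinase in nephron progenitors, together with a Rosa26 allele from which Cre switches on an activated Notch1 lacking its PEST domain. NICD_wt kidneys came from littermates without Cre. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

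The authors deposited a table of estimated counts per gene symbol and a table of TPM, transcript abundances normalised for gene length and depth, for the same libraries. The deposited estimated counts are whole numbers, so no further rounding was needed. The deposited TPM values have the same sum in each library. Per the submitters' processing notes, RSEM and Bowtie2 were used with the mm10 mouse genome; their versions, the gene annotation and the strand setting are not given in the sources used here. RSEM shares reads among near-identical genes by estimation, so values of close copies such as Hba-a1 and Hba-a2 are uncertain as single genes. Each table column was matched to its sample by name.

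The count table held 32793 genes, of which 12089 had no count in any library. Total counts ran from 17361823 to 21356447 per library, and 18253 to 19152 genes had a count. Counts were scaled with TMM factors of 0.9964 to 1.0054, genes were filtered with filterByExpr by group (minimum count 10, minimum total count 15), and 15885 genes were tested. The main test was the edgeR 4.0.16 quasi-likelihood test with robust dispersion in R 4.3.3, on NICD_mut against NICD_wt without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are NICD_mut minus NICD_wt, with standard errors (SE) from the fit, and levels are CPM, counts scaled to a common library size, given as mean ± SD.

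A set of 33 gene lists was tested or described. Lists with at least 3 tested genes, 28 in all, were set tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. The groups and the main test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the transgene genes and Notch targets, and the 10 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 1, non-overlapping groups and a standard symbol. It also took up to 4 members per list with the smallest adjusted p (2 where none passed) and any member that alone moved against its list; some genes that the rule takes are not reported here. The exclusion of libraries with muscle transcripts, the further lists in the closing section and the tests of explanations were chosen after the data had been seen.

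A gene with no count in a group is given as a bound from 3 counts over that group. A gene with 1 to 3 counts in a group is given as a ratio with a 95% counting interval. Such bounds and intervals cover counting error only. Gene coordinates are 1-based, from the GENCODE annotation of mm10, which was used for coordinates alone.

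The tests were checked on simulated counts for the same 15885 genes, 200 of them changed. The edgeR test recovered 37.7% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 87.5% of those changed 4-fold, and 14% of its calls were unchanged genes. In the data 47.7% of tested genes passed, far more than were changed in the simulation, so these shares need not hold there. In the simulated set tests a shifted list was called, as was 1 of 28 unshifted lists. Simulated genes were independent, so this does not check the preset correlation.

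Alternatives were DESeq2 size factors, library size alone, no filter and a stricter filter (50 counts in 2 samples). A minimum fold of 1.5, a replicate block, each library left out in turn, and erythroid genes left out were also tried. Other tests were DESeq2 1.42.0, limma-voom, and limma on log2 TPM with pseudocounts of 1 and 0.1. Set tests were repeated with an estimated correlation and with fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.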

Results

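Whole kidneys from mouse embryos at embryonic day 15.5 were profiled by bulk RNA sequencing. NICD_mut kidneys (2 libraries) expressed activated Notch1 in nephron progenitors, and NICD_wt kidneys (3 libraries) were from littermates without Cre. The comparison asks how sustained Notch1 activity in progenitors alters the nephron segments that form. Every NICD_mut library also carried the Cre driver and no NICD_wt library did. Effects of the driver and of activated Notch1 therefore cannot be told apart in any result below. Libraries held 17361823 to 21356447 counts. Across genes, log2 CPM of the NICD_wt libraries correlated with Pearson r of 0.9836 to 0.9875, against 0.9609 for the NICD_mut pair and 0.9125 to 0.938 between groups; genes are not independent replicates. The first principal component held 67.3% of the variance and the second 19.6%.

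NICD_mut kidneys had almost no Six2 transcript and very low levels of distal tubule and loop of Henle transporters, while most podocyte and proximal tubule markers were higher. Nephron progenitor markers fell in 16 of 20 cases, loop of Henle markers in 10 of 15 and distal tubule markers in 8 of 10 tested. Podocyte markers rose in 15 of 21 cases and proximal tubule markers in 26 of 40. In all, 7583 of 15885 tested genes (47.7%) passed the edgeR quasi-likelihood test, 3649 higher and 3934 lower in NICD_mut. At least a 2-fold change was seen for 1259 of the higher and 637 of the lower genes. The groups did not overlap for 67.2% of tested genes, where chance gives 20%. Of changed genes 48.1% were higher, with 47.4 and 48.9% under other scalings of the counts. By limma on log2(TPM + 1), which differs in unit, filter and test, 60.7% were higher, and the median of all genes shifted by 0.117 (log2). On counts, limma-voom gave 48% and a shift of -0.001, and edgeR with no filter gave 46.3%. TPM with no filter gave 61.8% and a shift of 0.115. These values argue against the filter or the use of limma as the source of the shift.

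Notch1, on chromosome 2 (mm10, 26457903 to 26516663, minus strand), encodes the receptor from which the transgene is derived. Its level was 306 ± 25.8 CPM in NICD_mut (SD, n = 2) and 130 ± 10.9 CPM in NICD_wt (SD, n = 3). The difference was 1.24 log2 (SE 0.08; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.03e-05). Reads of the transgene and of the endogenous gene are not separated in a count per gene. Six2, the transcription factor that maintains nephron progenitors (chromosome 17, 85684277 to 85688274, minus strand), had 7 and 6 counts in NICD_mut against 2667, 3015 and 2411 in NICD_wt, a log2 fold change of -8.76 (SE 0.12). Its neighbour Six3 (chromosome 17, 85613608 to 85629302, plus strand) had 15 and 19 counts in NICD_mut and 0 in each NICD_wt library, at least 15.97-fold higher.

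Among 9 Notch targets, 4 rose, 2 fell and 3 did not pass, with the same counts adjusted over the list alone. The transcriptional repressors Hey2 and Heyl rose by 1.44 (SE 0.15) and 1.38 (SE 0.15) log2, the feedback inhibitor Nrarp by 0.58 (SE 0.15) and the receptor Notch3 by 0.70 (SE 0.10). Hes5 had a log2 change of -3.82 (SE 0.30) and Lfng, a glycosyltransferase that modifies Notch receptors, of -0.94 (SE 0.15). Hes1 was at 57.1 ± 3.43 CPM (SD, n = 2) against 57.3 ± 2.39 (SD, n = 3), and neither it, Hey1 (0.77, SE 0.37) nor Dtx1 (-0.51, SE 0.21) passed. The list median was 0.58 and its mean -0.04, and the list did not pass (camera, Benjamini-Hochberg adjusted p = 0.455). Without NICD_mut 1, which left a lone NICD_mut library, the list median was 0.62, with Hey1 at 1.21 and Dtx1 at -0.92. Without NICD_mut 2 the list median was 0.14, Hey1 was at 0.14, and neither passed. Nrarp stayed at 0.57 to 0.60 log2 but no longer passed when any NICD_wt library was left out (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p of 0.0617 to 0.0869). Of 11 tested Notch ligands, other receptors and cofactors, 3 rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone; Dll1, a ligand, changed by -1.96 (SE 0.11) and Notch2 by 0.53 (SE 0.07). The number that rose was 6 without NICD_mut 1, 5 without NICD_wt 2, 2 without NICD_wt 1 or 3, and 8 by limma on log2(TPM + 1). That list did not pass (camera, Benjamini-Hochberg adjusted p = 0.194).

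**Figure D1:**
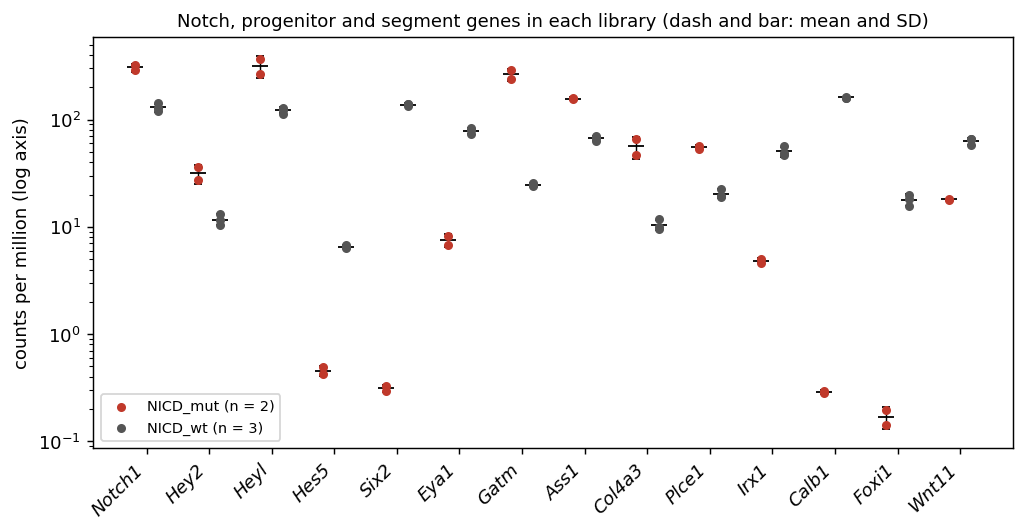
Normalised counts (CPM, log axis) of Notch pathway, progenitor and segment genes; points are libraries (2 NICD_mut, 3 NICD_wt), with a dash and bar for mean and SD. The 2 NICD_mut points for Notch1 lie above the 3 NICD_wt points, and those for Six2, Eya1, Irx1, Calb1 and Foxi1 lie below.

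Nephron progenitor genes were lower as a group. Of 20, 16 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone, and the median was -1.42. Besides Six2, the homeobox gene Uncx changed by -5.32 (SE 0.12), the proteoglycan Spock2 by -3.73 (SE 0.10) and the Six2 cofactor Eya1 by -3.38 (SE 0.12). Dpf3 alone rose, by 0.87 (SE 0.21), and at 0.59 did not pass without NICD_mut 2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0526). The progenitor list passed (camera, Benjamini-Hochberg adjusted p = 3.22e-13); the adjusted p = 0.0981 with an estimated correlation. Of 13 genes of the induced nephron, 6 fell, 3 rose and 4 did not pass (4 rose adjusted over the list alone). Their median was -0.22, and -0.04 without NICD_mut 1. By the DESeq2 Wald test 5 rose. Fgf8, which nascent nephrons need, changed by -5.99 (SE 0.43; -7.17 without NICD_mut 1 and -5.38 without NICD_mut 2), Bmp2 by -2.53 (SE 0.16) and the Wnt inhibitor Dkk1 by -2.23 (SE 0.14). This list did not pass (camera, Benjamini-Hochberg adjusted p = 0.0923), but passed with replicate number as a block (camera, Benjamini-Hochberg adjusted p = 0.00802).

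Markers of podocytes, the filtering epithelium of the glomerulus, were mostly higher. Of 21, 15 rose, 2 fell and 4 did not pass (16 rose adjusted over the list alone), with a median of 0.89, and 0.55 without NICD_mut 2. Col4a3, a collagen of the glomerular basement membrane, rose by 2.42 (SE 0.16), Plce1 by 1.43 (SE 0.10), and the slit diaphragm gene Kirrel by 0.65 (SE 0.08). The podocyte list passed (camera, Benjamini-Hochberg adjusted p = 1.1e-05); the adjusted p = 0.39 with an estimated correlation.

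Proximal tubule markers were also mostly higher. Of 40, 26 rose, 5 fell and 9 did not pass (27 rose and 6 fell adjusted over the list alone), with a median of 0.86. Gatm, an enzyme of creatine synthesis, rose from 24.8 ± 0.876 CPM (SD, n = 3) to 264 ± 34.6 CPM (SD, n = 2), a log2 change of 3.41 (SE 0.09; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.99e-08). The amino acid transporter Slc7a8 rose by 1.66 (SE 0.08), Keg1 by 1.35 (SE 0.07) and the urea cycle enzyme Ass1 by 1.23 (SE 0.07). The 5 that fell, named after their values were seen, were Slc13a3, Cubn, Slc22a6, Fbp1 and Kap; the number was 3 without NICD_wt 2 or 3 and with the replicate block, and 2 by limma on log2(TPM + 1). The proximal tubule list passed (camera, Benjamini-Hochberg adjusted p = 2.41e-08); the adjusted p = 0.342 with an estimated correlation.

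Genes of the loop of Henle and distal tubule showed the lowest list medians in the main fit. The ureteric tip median was below that of the distal tubule with no filter (-1.93 against -1.57) and without NICD_mut 1 (-2.88 against -2.17). In the loop of Henle list 10 of 15 fell, 1 rose and 4 did not pass (2 rose adjusted over the list alone), with a median of -3.78. Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, was at 0.446 ± 0.630 CPM (SD, n = 2) against 142 ± 19.3 CPM (SD, n = 3). Its log2 fold change was -8.27, and -8.28 with the replicate block, where it did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0623). NICD_mut 2 had 0 counts of it, and without that library the change was -7.32. Irx1 changed by -3.38 (SE 0.13), Irx2 by -5.36 (SE 0.29) and the tight junction gene Cldn19 by -7.64 (SE 0.45; -9.08 without NICD_mut 1 and -6.97 without NICD_mut 2). Ptger3, a prostaglandin receptor, rose by 1.59 (SE 0.25). The loop of Henle list passed (camera, Benjamini-Hochberg adjusted p = 9.53e-06); the adjusted p = 0.39 with an estimated correlation. In the distal tubule list 8 of 10 tested genes fell, 0 rose and 2 did not pass, with the same counts adjusted over the list alone and a median of -2.29. Calb1, a calcium-binding protein, was at 0.289 ± 0.0103 CPM (SD, n = 2) against 161 ± 0.680 CPM (SD, n = 3), a change of -9.09 (SE 0.11). Counts from whole kidneys do not show which cells the Calb1 transcripts came from. Tfap2b changed by -5.07 (SE 0.12) and Sostdc1 by -3.03 (SE 0.12). The distal tubule list passed (camera, Benjamini-Hochberg adjusted p = 3.15e-09); the adjusted p = 0.187 with an estimated correlation.

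Genes of the ureteric epithelium, which does not derive from the nephron progenitors, were also lower. Of 12 ureteric tip genes 7 fell, 1 rose and 4 did not pass, with the same counts adjusted over the list alone, and the median was -1.91; without NICD_mut 1, 9 fell, 2 rose and the median was -2.88. Ret, the receptor that drives branching, changed by -4.12 (SE 0.32; -4.79 without NICD_mut 1) and Wnt11 by -1.80 (SE 0.09), while Adamts18 rose by 1.08 (SE 0.20). The ureteric tip list passed (camera, Benjamini-Hochberg adjusted p = 0.00013); the adjusted p = 0.273 with an estimated correlation. Of 17 collecting duct genes 11 fell, 1 rose and 5 did not pass (12 fell adjusted over the list alone), with a median of -1.40. Foxi1, the intercalated cell regulator, changed by -6.68 (SE 0.27), Wnt9b by -3.38 (SE 0.17) and Hoxb7 by -1.21 (SE 0.09), while the keratin Krt8 rose by 0.73 (SE 0.11). The collecting duct list passed (camera, Benjamini-Hochberg adjusted p = 3.23e-06); the adjusted p = 0.187 with an estimated correlation. Of 7 urothelium genes 0 passed, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.729). The NICD_mut libraries moved this list in opposite directions: without NICD_mut 2, 5 of 7 rose at a median of 1.49, and without NICD_mut 1, 2 fell at a median of -1.45.

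**Figure D2:**
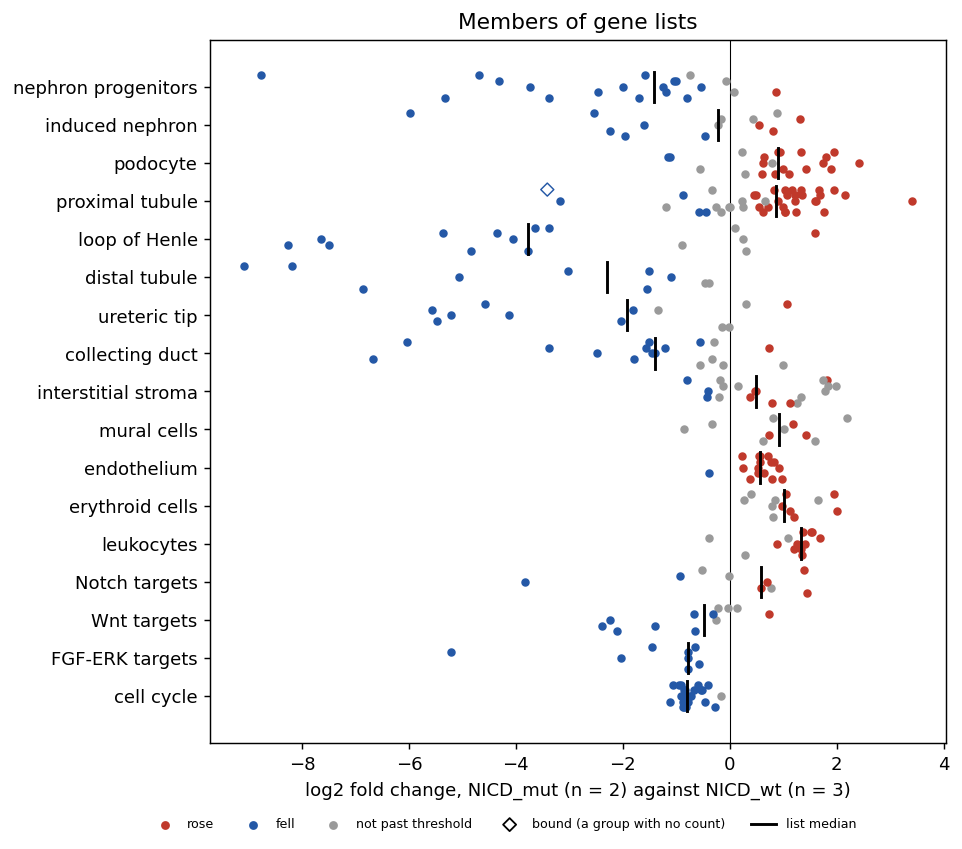
Log2 fold change (NICD_mut, n = 2, against NICD_wt, n = 3) of each tested member of 17 gene lists; filled points are genes, coloured by whether they rose, fell or did not pass, open diamonds are bounds for genes with no count in a group, and bars are list medians. Medians run from -3.78 for the loop of Henle to 1.33 for leukocytes.

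Endothelial, red cell and macrophage markers were higher. Of 16 endothelial genes 15 rose and 1 fell, also adjusted over the list alone, with a median of 0.57; the growth factor receptor Kdr rose by 0.98 (SE 0.08) and the junction gene Cdh5 by 0.84 (SE 0.07), while Ehd3 changed by -0.40 (SE 0.10). Of 12 erythroid genes 6 rose and 6 did not pass (7 rose adjusted over the list alone), with a median of 1.01; Alas2, the first enzyme of red cell heme synthesis, rose by 1.05 (SE 0.10). Erythroid transcripts made up 1.02 and 1.14% of counts in NICD_mut against 0.451 to 0.581% in NICD_wt. Of 13 leukocyte genes 10 rose and 3 did not pass (11 rose adjusted over the list alone), with a median of 1.33; the macrophage receptor Csf1r rose by 1.69 (SE 0.10). These lists passed (camera, Benjamini-Hochberg adjusted p = 1.58e-05, 0.000406 and 1.31e-05 in that order), with adjusted p = 0.39, 0.39 and 0.187 with an estimated correlation.

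Stromal markers went both ways, and most mural markers did not pass. Of 19 stromal genes 6 rose, 3 fell and 10 did not pass, and of 10 mural genes 3 rose and 7 did not pass, with the same counts adjusted over each list alone. The matrix enzyme Lox rose by 1.13 (SE 0.13), Penk changed by -0.80 (SE 0.12), and the pericyte gene Cspg4 rose by 1.42 (SE 0.10). Neither list passed (camera, Benjamini-Hochberg adjusted p = 0.102 and 0.0941). The mural median was 0.91, and -0.25 without NICD_mut 1. The stromal median was 0.5, and 0.44 without NICD_mut 1. Without NICD_wt 3, 1 mural gene fell. By the DESeq2 Wald test 12 stromal genes rose and 3 fell. Fits without NICD_mut 2 keep only NICD_mut 1, the library with most muscle transcripts, and have no spread within NICD_mut. Leaving out NICD_mut 1 and NICD_wt 1, an exclusion chosen after the data were seen, also keeps 1 NICD_mut library and has the same limit.

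Skeletal muscle genes set NICD_mut 1 apart. They took 0.330% of its counts, 0.001% of those of NICD_mut 2, 0.014% of those of NICD_wt 1, and 106 and 80 counts in NICD_wt 2 and 3. Of 8 muscle genes 0 passed, also adjusted over the list alone, at a median of 4.96 (camera, Benjamini-Hochberg adjusted p = 0.218). Without NICD_mut 1, 7232 genes passed, and 0 of 8 muscle genes, at a median of -1.31; without NICD_wt 1 alone their median was 8.95. Without NICD_mut 1 and NICD_wt 1, an exclusion chosen after the data were seen, 6898 genes passed, and 3 of 8 muscle genes rose at a median of 1.5. By the DESeq2 Wald test and with the replicate block 2 muscle genes rose, and the list passed with the block (camera, Benjamini-Hochberg adjusted p = 0.00185). Of 7 liver genes 2 rose and 5 did not pass, also adjusted over the list alone; Fgb, a fibrinogen chain, rose by 4.46 (SE 0.16) while Afp was at -0.18 (SE 0.18) and did not pass. Of 6 peripheral glia genes 4 rose and 2 did not pass (5 rose adjusted over the list alone), and of 7 adrenal and sympathetic genes 3 rose, 1 fell and 3 did not pass, also adjusted over the list alone. Only 1 liver gene rose without NICD_mut 1 or NICD_wt 1. The glia genes that rose numbered 1 without NICD_mut 1, NICD_wt 2 or NICD_wt 3, 2 without NICD_wt 1, and 0 with the replicate block. The adrenal genes that rose numbered 1 without NICD_mut 1 or NICD_wt 1. These 3 lists did not pass (camera, Benjamini-Hochberg adjusted p = 0.104, 0.102 and 0.442). The liver list passed without NICD_wt 2 and with the replicate block (camera, Benjamini-Hochberg adjusted p = 0.0418 and 0.0297). A fit without NICD_mut 2 rests on NICD_mut 1 alone, so its set tests of the liver and glia lists have no spread within NICD_mut. The 1 gonad gene tested, Dhh, did not pass.

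**Figure D3:**
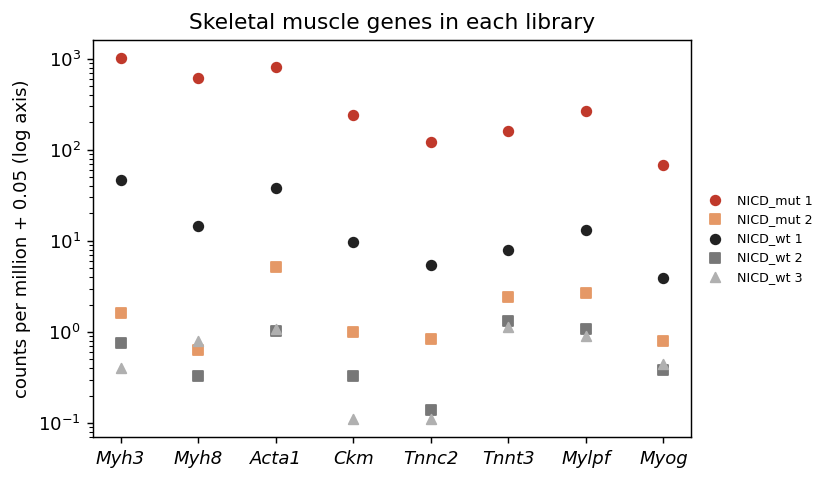
Normalised counts (CPM plus 0.05, log axis) of 8 skeletal muscle genes in each of the 5 libraries. NICD_mut 1 lies 17.8 to 42.3 times above NICD_wt 1, the next highest library.

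Proliferation genes and signalling feedback genes were lower. Of 23 cell cycle genes 22 fell and 1 did not pass, also adjusted over the list alone, with a median of -0.81; the cyclin Ccnb1 changed by -1.06 (SE 0.07) and the kinase Bub1 by -1.12 (SE 0.07), and Mki67 did not pass (-0.16, SE 0.11). Each of 8 FGF-ERK feedback genes fell, also adjusted over the list alone, with a median of -0.78; Spry1 changed by -1.45 (SE 0.09). Of 12 Wnt targets 7 fell, 1 rose and 4 did not pass, also adjusted over the list alone, with a median of -0.48; Lef1 changed by -1.40 (SE 0.16) and Axin2 by -0.66 (SE 0.08), while Notum rose by 0.73 (SE 0.15). These 3 lists passed (camera, Benjamini-Hochberg adjusted p = 3.78e-13, 1.69e-06 and 0.00408 in that order), with adjusted p = 0.104, 0.187 and 0.187 with an estimated correlation. Of 6 BMP targets 2 rose, 2 fell and 2 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.912); 1 rose without NICD_mut 2, NICD_wt 1 or NICD_wt 3.

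Stress lists were mixed. Of 12 immediate early and heat shock genes 7 rose and 5 did not pass, also adjusted over the list alone, with a median of 0.44; the transcription factor Jun rose by 1.11 (SE 0.06). This list passed (camera, Benjamini-Hochberg adjusted p = 0.0222); the adjusted p = 0.39 with an estimated correlation, and it did not pass without NICD_mut 1, without NICD_mut 1 and NICD_wt 1, or with the replicate block (camera, Benjamini-Hochberg adjusted p = 0.0628, 0.088 and 0.0516). Of 14 p53 targets 6 rose, 2 fell and 6 did not pass (7 rose and 3 fell adjusted over the list alone), with Pmaip1 2.30 (SE 0.24) higher. Of 12 hypoxia targets 1 rose, 4 fell and 7 did not pass, also adjusted over the list alone, with Ndrg1 2.46 (SE 0.07) higher and the glycolytic enzyme Pgk1 at -0.89 (SE 0.06). Of 7 tubule injury genes 2 rose, 1 fell and 4 did not pass, also adjusted over the list alone, with Vcam1 1.90 (SE 0.13) higher and Lcn2 at -2.54 (SE 0.50). These 3 lists did not pass (camera, Benjamini-Hochberg adjusted p = 0.21, 0.482 and 0.218). The p53 target median was 0.32, and 0.14 without NICD_mut 1. The tubule injury median was 1.01, and -0.21 without NICD_mut 1. A fit without NICD_mut 2 rests on NICD_mut 1 alone and has no spread within NICD_mut.

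Of the 10 largest rises taken by the rule, 0 were members of the 33 lists. Nmur2, a neuropeptide receptor, had no count in NICD_wt and was at least 212-fold higher. Grin2b, a glutamate receptor subunit, rose by 8.06 (SE 0.38; 8.81 without NICD_wt 3), the chemokine Cxcl10 by 8.02 (SE 0.68; 7.16 without NICD_mut 1), the hemoglobin-binding plasma protein Hp by 7.35 (SE 0.46) and the mitochondrial folate enzyme Aldh1l2 by 5.65 (SE 0.15). Among the largest falls, Defb1, an antimicrobial peptide, had no count in NICD_mut and was at least 106-fold lower. Bsnd, with 2 and 0 counts in NICD_mut, was lower by a ratio of 390 (95% counting interval 108 to 3224). Its log2 fold change was -8.42, and -7.55 without NICD_mut 2. Without NICD_mut 1 no NICD_mut count of Bsnd is left.

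Quality lists showed no group difference that passed. Lars2 was the only ribosomal RNA remnant list member in the table and did not pass, and 0 mitochondrial mRNAs were in it. All 5 libraries had Y-linked Ddx3y counts, between 1545 and 2033. Xist, the X-inactivation transcript of females, had 5 and 11 counts in NICD_mut and 137, 6 and 12 in NICD_wt; 0 of the 5 genes of this list passed.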

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

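The exclusion of both libraries with most muscle transcripts was chosen after the data were seen; the other alternatives were planned. Counts of changed genes stayed within 1.5 times of 7583 apart from those given here. A minimum fold of 1.5 left 1695 genes, 998 higher and 697 lower, because the test asks for more. The unfiltered TPM test called 2606 lower genes. The filter is argued against as the main source, since the filtered TPM test called 2785 and edgeR with no filter 4027. Leaving out a library gave 5898 to 8050 changed genes (2797 to 3843 higher, 3101 to 4207 lower), with 14 to 21 lists; a lone NICD_mut library is then assumed to vary like the NICD_wt ones. All genes changed at least 2-fold that had a value kept their direction in each of the 18 settings. Of 125 named genes past the threshold, 85 passed wherever they had a value. Both sets were chosen by the main fit, and the settings reuse its libraries. Agreement was therefore largely built in and is not a separate check.

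With an estimated correlation 0 lists passed camera, against 14; the lowest adjusted p was 0.0981. By fry, 18 lists moved in 1 direction and 25 in either. The erythroid list was not called when its own genes were left out.

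Replicate numbers are shared between groups but nothing in the labels pairs the samples. Deviations from the group mean of same-numbered libraries correlated at 0.34 (number 1) and 0.149 (number 2), and NICD_mut 2 correlated more with NICD_wt 3 (0.234). With 2 NICD_mut libraries their deviations are mirror images. These values are therefore not separate checks and cannot decide whether the samples are paired. Some genes, picked after their values were seen, had like counts in NICD_mut 2 and NICD_wt 2. Rpl30 had 5732 and 3675 there, against 170, 239 and 200 in NICD_mut 1, NICD_wt 1 and NICD_wt 3. Rps29 had 3451 and 3546, against 5354, 6312 and 5328. Lars2 went the other way, with 6063 in NICD_mut 2 and 3191 in NICD_wt 2. A batch by replicate number is thus left open. A replicate block gave 5535 genes. In simulated data, 50.2% of its calls were unchanged genes. Far fewer genes were changed in the simulation than passed in the data. That share therefore need not hold for the 5535 genes and cannot decide whether the block is sound. NICD_wt 3 shares its replicate number with no other library, so it adds nothing to the group difference under the block.

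Sex was not run as a covariate, since all libraries carried Y-linked transcripts. Such transcripts do not show that each library was male only. Xist was at 6.9 CPM in NICD_wt 1, against 0.23 to 0.69 CPM in the other libraries. A mixed or pooled NICD_wt 1 is therefore left open. Depth limits genes with few counts, for which bounds or intervals are given.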

Other observations

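The lists and tests in this part were all chosen after the results they bear on had been seen. Of 82 tested cytosolic ribosomal protein genes 74 fell, 0 rose and 8 did not pass, with a median of -0.54 (camera, Benjamini-Hochberg adjusted p = 7.29e-19; adjusted p = 0.211 with an estimated correlation). They took 4.15 and 4.28% of counts in NICD_mut and 5.85 to 6.31% in NICD_wt. Of 16 interferon response genes, listed after Cxcl10 was seen and without it, 9 rose, 1 fell and 6 did not pass, with a median of 0.94; Irf1 rose by 1.24 (SE 0.14). That list passed (camera, Benjamini-Hochberg adjusted p = 0.00521; adjusted p = 0.211 with an estimated correlation).

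Aldh1l2 rose by 5.65 (SE 0.15) and Stc2 from 6.21 ± 1.21 CPM (SD, n = 3) to 198 ± 43.2 CPM (SD, n = 2), and both are known targets of the integrated stress response. Of 21 other genes of that response 3 rose, 9 fell and 9 did not pass, with a median of -0.31 (camera, Benjamini-Hochberg adjusted p = 0.0187; adjusted p = 0.211 with an estimated correlation), so the list did not move with them. Of 6 tested acute phase genes 4 rose, 1 fell and 1 did not pass (camera, Benjamini-Hochberg adjusted p = 0.029; adjusted p = 0.211 with an estimated correlation). Kcnj11 and Abcc8, the subunits of the ATP-sensitive potassium channel, rose by 4.34 (SE 0.21) and 3.44 (SE 0.24), and the homeobox gene Nkx6-1 by 4.29 (SE 0.35).

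Six3 had counts in both NICD_mut libraries and in 0 of the NICD_wt libraries. Misassigned Six2 reads are argued against: Six3 summed to 0 counts in NICD_wt, where Six2 summed to 8093. The Cre driver is built from the Six2 locus, and Six3 lies 55.0 kb from Six2 in the reference, so a candidate explanation is that the driver's artificial chromosome carries Six3. At a mean of 0.82 CPM this cannot be told apart from an effect of activated Notch1, because every library with Cre also has activated Notch1.

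Skeletal muscle transcripts were high in NICD_mut 1. Over 18 further muscle genes the median ratio of NICD_mut 1 to NICD_mut 2 was 20.9 (95% bootstrap interval over genes 14.8 to 45.2). The 2 NICD_mut libraries thus did not share a rise of like size. This restates the pattern in more genes and is not a separate test of its cause. Muscle genes move together (estimated correlation 0.992 in the planned list), so the interval does not measure spread between libraries. That comparison is the third tried; in the others the median ratio of NICD_mut 2 was 0.496 to NICD_wt 1, the highest control, and 1.165 to the higher of NICD_wt 2 and 3 (interval 0.785 to 1.648), which leaves a small rise in NICD_mut 2 open. Carry-over of muscle tissue at dissection may account for the level in NICD_mut 1. Of these genes 88.9% (16 of 18) were at least 5 times higher in NICD_mut 1 than in every other library, just under the 90% set for the test, so it stays open; the exceptions were Pygm and Jsrp1.

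Proximal tubule markers were higher. Scaling by a factor per library, which moves all genes alike, is argued against. The list median lay 0.85 above that of all tested genes (log2, 95% bootstrap interval 0.46 to 1.11). This difference restates the list median of 0.86 against 0.013 for all tested genes, so it is not a separate test of the pattern. It replaced a first comparison over 5 scalings, where the lowest list median was 0.86. The bootstrap interval resamples genes, and the permutation tests below shuffle genes among lists. Genes of a list are correlated (estimated at 0.22 for proximal tubule and 0.484 for endothelium), so neither measures spread between libraries. Loss of other cells could also raise markers of the remaining types alike. The medians of 6 such lists spanned 0.83 (permutation p = 0.11), and 1.55 without NICD_mut 1 (permutation p = 0.0017). A second test of this idea was added because the first was undecided, and was tried at first against endothelium alone, where the proximal tubule list spread more (one-sided permutation p = 0.00029); over all 5 other lists that held for 2 with and without NICD_mut 1, and the highest p was 0.75, so loss of other cells and a change in the proximal tubule cannot be told apart here.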
